A study of Drosophila melanogaster with 3 samples.

How the data were processed

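RNA recovered with Smn was measured by RNA immunoprecipitation followed by sequencing (RIP-seq) in S2R+ cells, an established cell line of Drosophila melanogaster. Smn is the fly form of the survival motor neuron protein, which takes part in assembling small nuclear ribonucleoproteins. Per the labels, the cells carried tagged Smn under a metallothionein promoter and were exposed for 24 hours to copper(II) sulfate at 0.35 mM. The labels give 3 biological replicates of this 1 group. A control experiment that the labels mention as possible was not analysed here, so every level below is abundance in the immunoprecipitate and not enrichment over input.

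The authors deposited 1 track per library with the signal of all reads, both strands together, on the dm3 build. The deposited signal is a read pile-up per base scaled per 1000000 reads, and replicates were not pooled. The aligner, its filters and the treatment of reads with several matching positions are not given in the sources used here. Within each track the values were whole multiples of 1 step, with a largest deviation of 2.91e-09 from a whole number. Signal times length gave 50 bases per read, and dividing 1000000 by the step gave the number of reads. This came to 27568960 reads for replicate 1, 3760899 for replicate 2 and 8468828 for replicate 3. Because strands were combined, transcripts from opposite strands of a region cannot be told apart. Reads without molecular identifiers are not independent molecules, so the exact Clopper-Pearson 95% intervals given for shares cover counting error only.

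The span of the tracks was divided into bins of 1000 bases, and the mean signal per base was taken in each bin and library. A bin counted as measured when its mean signal was at least 0.266 in all 3 libraries. In the shallowest library this is a mean depth of 1 read along the whole bin, which a single read does not reach. The same value served as pseudocount. Levels are log2(mean signal + pseudocount) minus the library's median over the 15535 measured bins, and folds on this scale understate the differences of low bins. Signal-rich bins were tested with limma 3.58.1 in R 4.3.3 (lmFit and treat), against a level of 2 on the log2 scale, which is 4-fold above the median bin. Calls needed a Benjamini-Hochberg adjusted p under 0.05. Adjacent called bins were merged into regions, and a region's level, SE and p are those of its highest bin. A region's signal is the mean over all its bins. Each SE is limma's moderated value, which draws the variance of a bin towards that of the other bins. It can therefore lie below or above the SE of the 3 replicate levels alone. Region coordinates are 1-based on dm3. A bin was called compact when 80% of its signal lay within 200 consecutive bases in every library.

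Replicates were compared by Pearson's r and Spearman's rho across bins, without p-values, because bins are not independent replicates. Library-specific bins were those lying over 2 on the log2 scale from both other libraries in 1 direction. With 1 library on one side, this count has no test. Shares of signal per sequence and the share held by the top 1% of covered bins were computed per library. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

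The rule for regions to be named was fixed before the data were examined: the 25 signal-rich regions with the highest mean level, and the 3 most extreme library-specific bins for each library and direction. Regions named outside this rule are marked as such. The gene lists and the ratio of intronic to exonic signal that had been planned were not run, because they need a dm3 annotation, which was not used here. Gene names were not attached to dm3 coordinates for the same reason, and Smn's own gene is not reported.

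The test was tried on simulated data over 15535 bins, with 50 bins set at each of 4 levels. Of these bins, 16% were recovered at a level of 3, 72% at 4, 84% at 5 and 94% at 7. There were 0 false calls among 15335 bins that were not raised. The unraised bins were set no higher than the tested level, so this 0 does not show how often the test errs. Recovery was not examined separately for bins with a large spread between replicates, such as those of regions outside the arms. The percentages therefore need not hold for them. The alternatives tried were other pseudocounts, filters, centrings, thresholds and bin sizes, the chromosome arms alone, and leaving out each replicate in turn. When a replicate was left out of the test, bins still had to be measured in all 3 libraries. Thinning each library to the reads of the shallowest was added after the data were seen.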

Results

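RNA recovered with Smn from copper-treated S2R+ cells was sequenced in 3 biological replicates of 1 group. The tracks covered 139.66 Mb of dm3, and the libraries held 27568960, 3760899 and 8468828 reads. Signal lay on 22.0% of the span in replicate 1, 9.75% in replicate 2 and 17.2% in replicate 3. No second group was analysed, so the regions described below are those most abundant in the immunoprecipitate, and their spread is that between the 3 replicates.

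Most signal lay on the chromosome arms 2L, 2R, 3L, 3R, 4 and X, with 76.1% ± 13.2 (SD, n = 3). The share on the arms was 91.3% in replicate 1, 69.4% in replicate 2 and 67.6% in replicate 3. U, the collection of unplaced dm3 sequence, held 14.3% ± 6.78, and XHet, the heterochromatic sequence assigned to the X chromosome, held 5.62% ± 4.12 on only 0.201 Mb. M, the mitochondrial genome, held 3.28% ± 2.59. Replicate 1 stood apart on each of these sequences. Its share on U was 6.45%, against 17.6% and 18.7% in replicates 2 and 3, and its share on XHet was 1.14%, against 6.49% and 9.25%. Most of the XHet share lay in the bin XHet 191001 to 192000, with 0.834%, 5.69% and 8.47% in replicates 1, 2 and 3. A large part of the gap on U lay in U 9063001 to 9065000, with 0.695%, 7.80% and 7.77%. On M, replicate 1 held 0.490% (95% interval 0.487 to 0.492), against 5.60% (5.58 to 5.63) and 3.75% (3.74 to 3.76). The mean for M was 2.12% without replicate 2. These gaps between libraries exceeded counting error, and with 1 group no test of them was made. Without the 0.1% of bins with the highest signal, the mean shares fell to 0.999% on U, 0.235% on M and 0.0622% on XHet.

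**Figure D1:**
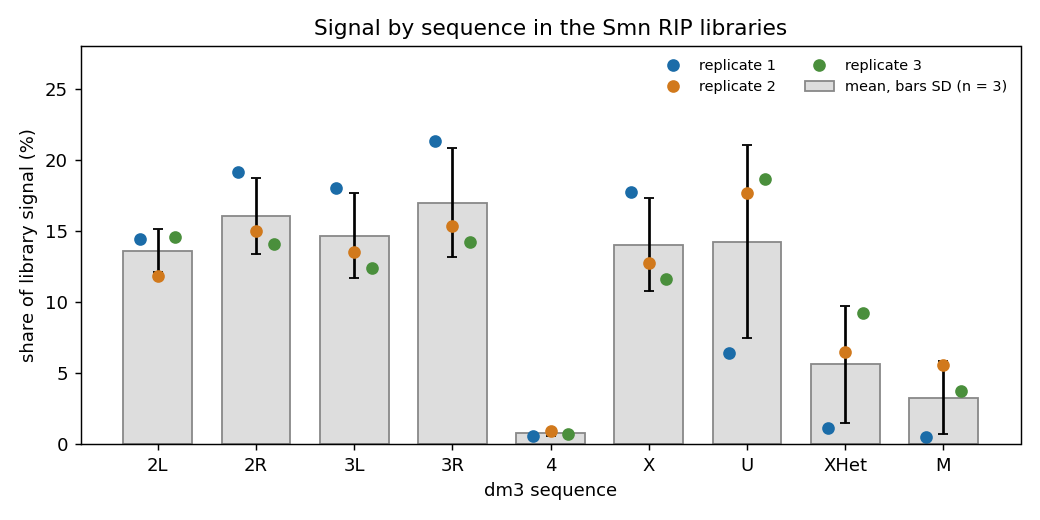
Share of each library's signal in percent on 9 dm3 sequences. Grey bars are means, black bars the SD over 3 replicates, and points the single libraries. Replicate 1 lies below the others on U (6.45%), XHet (1.14%) and M (0.490%).

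Signal was concentrated in few places. The top 1% of covered bins held 40.5%, 49.5% and 58.4% of the signal of replicates 1, 2 and 3, with a mean of 49.4% ± 8.93 (SD, n = 3). On the arms alone the shares were 35.5%, 29.5% and 40.0%, with a mean of 35.0% ± 5.26, so replicate 1 was not the lowest there. The top 1% was taken of each library's own covered bins, so the shares are over sets that can differ in size. The regions U 5726001 to 5728000, XHet 191001 to 192000 and U 9063001 to 9065000 together held 5.31% of replicate 1, 18.9% of replicate 2 and 22.7% of replicate 3. The highest single base lay at U 5727183 in replicate 1, under 504994 reads. It lay at U 9063674 in replicate 2, under 197672 reads, and at XHet 191915 in replicate 3, under 670638 reads.

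Across the 15535 measured bins, replicates 2 and 3 followed each other closely, with a Pearson r of 0.940 and a Spearman rho of 0.877. Replicate 1 followed them less, with r of 0.706 and 0.693 and rho of 0.607 and 0.597. Without the filter on low values, r rose to 0.902 in both pairs with replicate 1. Among the 1274 arm bins with at least 10 times the minimum signal, r was 0.944 for replicates 2 and 3 and 0.634 and 0.608 for the pairs with replicate 1. These correlations are across bins, which are not independent. Within those arm bins, coverage was least even in replicate 1. Its median coefficient of variation along a bin was 1.02, against 0.749 and 0.672, and it was the most uneven library in 88.2% of bins.

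The central question the design allows is which regions stood above the typical region of the same libraries. In limma's test against a 4-fold level, 277 of 15535 measured bins (1.78%) were signal-rich, and 592 had an unadjusted p under 0.05. The count was 673 without replicate 1, and the 277 bins were all among these 673. The bins tested there were still the 15535 measured in all 3 libraries, so replicate 1 still shaped which bins were tested. The called bins formed 197 regions, of which 179 lay on the arms and 137 were a single bin. The longest, 3L 827001 to 833000, which was chosen after its values were seen, spanned 6 bins at a mean signal of 36.0 ± 8.98 (SD, n = 3). Per Mb, the density of called bins on the large arms was 2.74 on 2R, 2.01 on X, 2.01 on 3R, 2.00 on 3L and 1.78 on 2L. Chromosome 4 had 2.97 per Mb, from 4 called bins. Outside the arms, 24 of 189 measured bins (12.7%) were called, compared with 253 of 15346 (1.65%) on the arms. Per Mb of sequence, called bins numbered 1.24 over all sequences outside the arms and 2.10 on the arms. The sequences outside the arms differed widely, with 250.0 per Mb on M, 14.9 on XHet and 1.39 on U.

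The region with the highest mean log2 level was U 5726001 to 5728000, at 10.94 (SE 0.287), with an adjusted p of 0.000152 in limma. Averaged over its 2 bins, its signal was 1300.3 ± 334.7 (pile-up per 1000000 reads, SD, n = 3). The single bin XHet 191001 to 192000 had 2499.7 ± 1932.8, and the 2 bins of U 9063001 to 9065000 averaged 1355.6 ± 1023.6. Averages over unlike numbers of bins do not rank the highest bins. Without replicate 1, the level was 11.57 at XHet 191001 and 11.29 at the highest bin of U 5726001 to 5728000. By level, XHet 191001 to 192000 followed at 10.42 (SE 0.674, limma adjusted p = 0.00113), and U 9063001 to 9065000 at 9.45 (SE 0.953, limma adjusted p = 0.00766). The SD of the level between replicates was 2.03 at XHet 191001 and 2.95 at U 9063001. Both of these were compact. At XHet 191001 the signal was 417 in replicate 1, 2846 in replicate 2 and 4236 in replicate 3, and at U 9063001 to 9065000 it was 174, 1950.1 and 1943. Next came U 4570001 to 4572000 at a level of 8.26 and the compact U 9660001 to 9661000 at 8.24. The remaining U regions among the 25 highest were the compact bins starting at 6962001, 3545001 and 8839001, at levels of 7.34, 5.83 and 5.70. On XHet, compact bins starting at 184001 and 194001 reached 6.85 and 6.48. With a pseudocount 10 times higher, the calls at XHet 191001, U 9063001, XHet 184001 and U 3545001 were lost, with limma adjusted p-values of 0.0704, 0.333, 0.208 and 0.995 at levels of 8.88, 7.91, 5.34 and 4.36.

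Mitochondrial RNA gave M 1001 to 3000, at a level of 7.68 (SE 0.688), and M 12001 to 15000, at 7.65 (SE 0.629). Their limma adjusted p-values were 0.00584 and 0.00373, and both calls were lost with a pseudocount 10 times higher (0.295 and 0.228, at levels of 6.16 and 6.12). Signal in M 1001 to 3000 was 51.2, 589 and 445 in replicates 1, 2 and 3, and in M 12001 to 15000 it was 38.2, 363 and 210.3. Of the 14 measured bins on M, 5 were called. All 12 of the highest regions that lay outside the arms were lowest in replicate 1.

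On the arms, 13 regions were among the 25 highest, and none of them was compact. The highest was 2R 7781001 to 7783000, at a level of 7.42 (SE 0.300, limma adjusted p = 0.000401) and a signal of 316, 142 and 155 in replicates 1, 2 and 3. On 3L, the regions 2587001 to 2589000, 16573001 to 16575000 and 653001 to 654000 had levels of 6.74, 6.64 and 6.07. On X, 9047001 to 9049000 reached 6.73, 18962001 to 18963000 reached 6.54, and 5796001 to 5799000 reached 6.33. On 2L, 22427001 to 22430000 stood at 6.65, 21678001 to 21682000 at 6.40 and 9896001 to 9897000 at 5.72. On 3R, 5609001 to 5611000 stood at 6.38, 25046001 to 25048000 at 6.15 and 19183001 to 19186000 at 5.71. The SD of these arm levels between replicates ranged from 0.0841, at 2L 22427001, to 0.731, at 3R 5609001. For the 12 regions outside the arms it ranged from 0.590 to 2.95. The levels of 3L 2587001, X 9047001 and 2L 22427001 (6.74, 6.73 and 6.65) differed by less than the spread of the most variable of them, so their order is not resolved. On the centred scale, replicate 1 was the lowest library at the highest bin of 6 of the 13 arm regions and the highest library at another 6. On the deposited scale it was lowest at 2 and highest at 9.

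**Figure D2:**
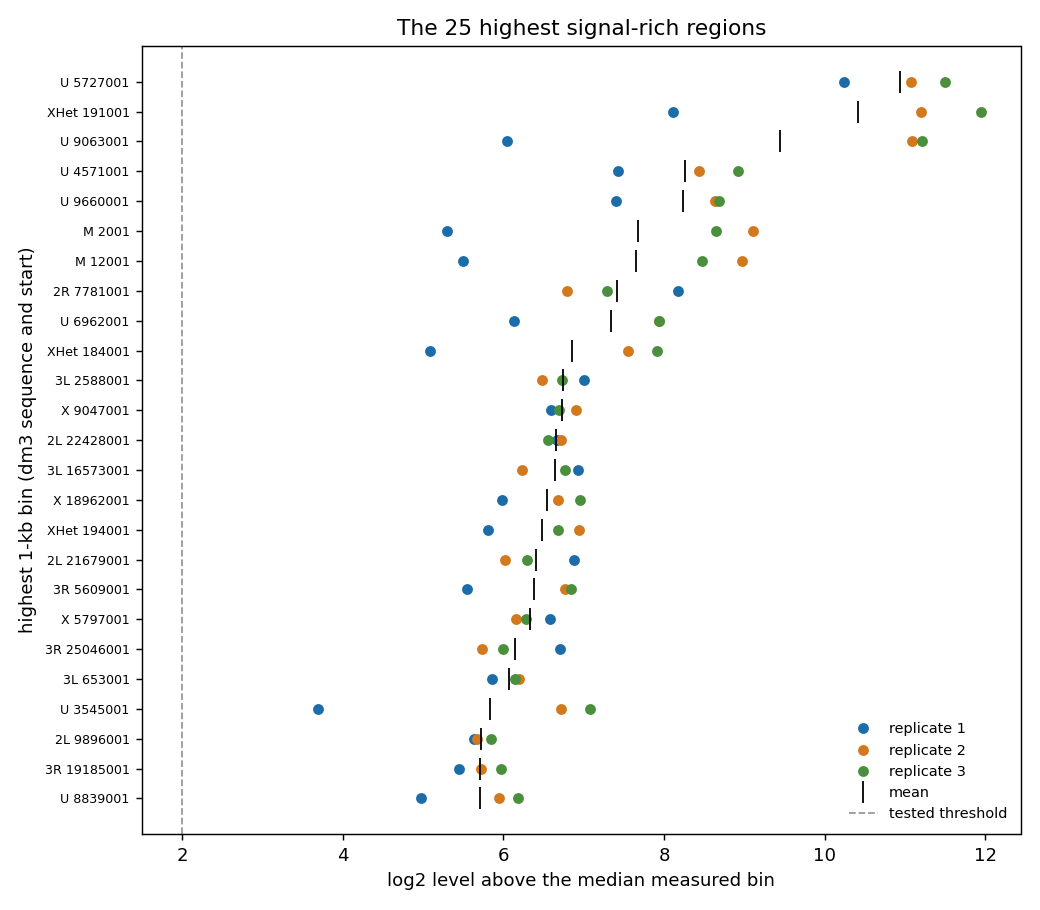
Log2 level above the median measured bin for the highest bin of each of the 25 highest signal-rich regions, from 5.70 to 10.94. Points are the 3 replicates, ticks their mean, and the dashed line the tested level of 2. Replicate 1 lies lowest in all 12 regions on U, XHet and M.

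Several bins had a high mean level but varied too much between replicates to pass the test. X 5726001 to 5727000 had a signal of 10.1 in replicate 1, 433 in replicate 2 and 512 in replicate 3, and its adjusted p in limma was 0.0992 at a level of 6.72. The bin before it, X 5725001 to 5726000, had 2.56, 114 and 113 (limma adjusted p = 0.621). 2L 13211001 to 13212000 had 8.95 in replicate 1, 86.4 in replicate 2 and 1217 in replicate 3, with an adjusted p of 0.206 in limma. M 11001 to 12000, chosen after its values were seen, had 12.2, 162 and 119 (limma adjusted p = 0.0549).

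Replicate 1 also held most of the library-specific bins. It was over 4-fold higher than both others in 119 bins and over 4-fold lower in 263. On the deposited scale, without centring, these counts were 327 and 129, so the balance of higher and lower bins depends on the scale. The most extreme higher bins were X 16345001 to 16346000 (92.9 against 4.51 and 2.85), 3L 21828001 to 21829000 (25.7 against at most 2.08) and X 16453001 to 16454000 (16.1 against 1.28 and 1.06). The most extreme lower bins were M 5001 to 6000 (0.866 against 75.1 and 51.4) and the pair X 5726001 and X 5725001 given above. Of the 263 lower bins, 215 (81.7%) lay on the arms, which hold 98.8% of all measured bins. All 14 measured bins of M were among the lower ones, as were 21 of the 70 measured bins of U. Replicate 2 had 0 such bins in either direction. Replicate 3 had 9 higher and 0 lower, led by 2L 21215001 to 21216000 (376 against 2.14 and 24.5), 2L 13212001 to 13213000 (293 against 1.60 and 19.5) and 2L 13211001 to 13212000. With at least 10 times the minimum signal in every library, 1320 of the 15535 measured bins remained. Among these the counts were 16 and 47 for replicate 1 and 1 for replicate 3. That filter also leaves out bins low in any 1 library, so the smaller counts do not show a smaller proportion. These contrasts set 1 library against 2, so no test was made.

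**Figure D3:**
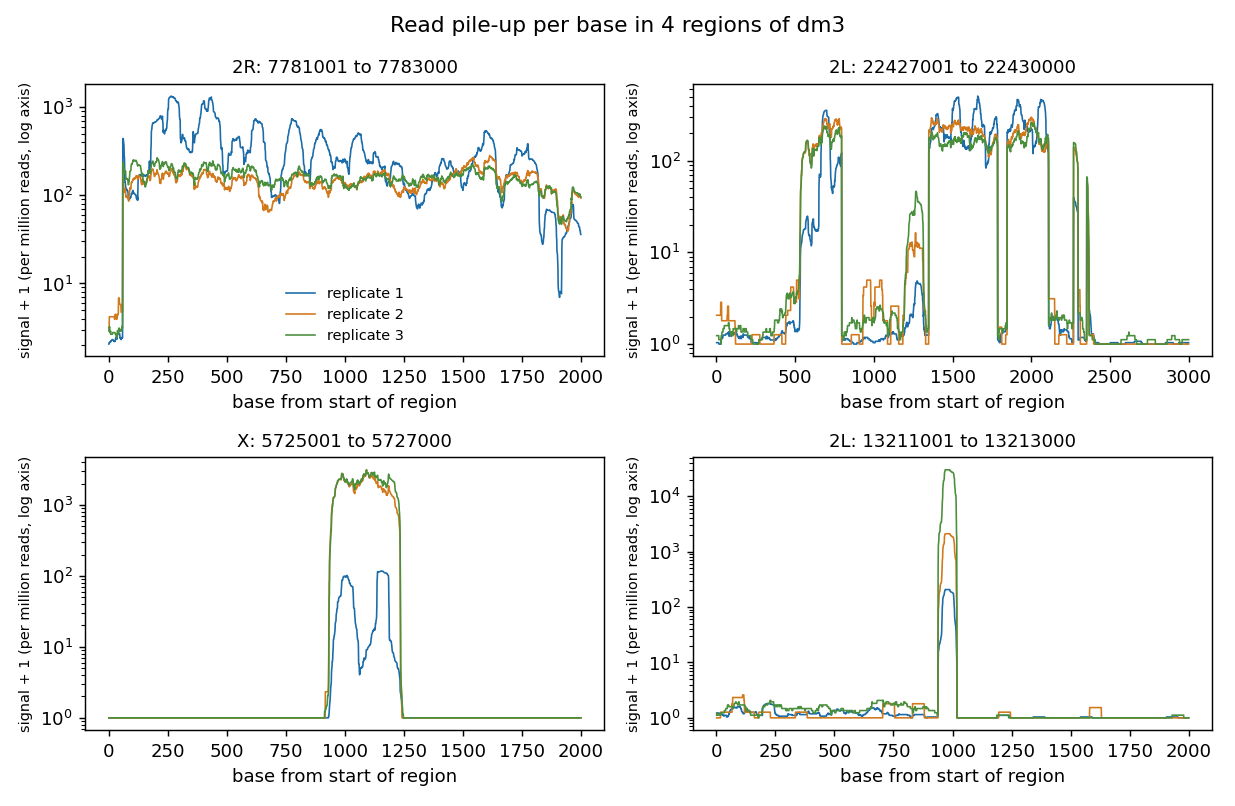
Read pile-up per base (signal + 1 per 1000000 reads, log axis) for the 3 replicates in 4 dm3 regions. The broad 2R 7781001 and 2L 22427001 regions are covered by all replicates, and narrow blocks mark X 5725001 to 5727000, low in replicate 1, and 2L 13211001 to 13213000, highest in replicate 3.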

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

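All tests of explanations in this part were chosen after the result was seen, except those on uneven coverage and on the broad bins of M. The libraries form 1 group, so the design gives no biological difference between them to test.

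Reads appeared on YHet, a Y-chromosome sequence on which no bin reached the measured level. There were 126 in replicate 1, 4 in replicate 2 and 13 in replicate 3, and they are listed because each count exceeds 3 reads. Whether these reads come from YHet was not tested.

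Among bins that fell below the minimum in at least 1 library, 40 had strong signal in another. The highest was 3R 773001 to 774000, chosen after its values were seen, with a signal of 86.9 in replicate 3, 3.91 in replicate 2 and 0.0651 in replicate 1. Of the 40, 27 were highest in replicate 1, 3 in replicate 2 and 10 in replicate 3.

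Replicate 1 differed from replicates 2 and 3 across bins of the arms. Over 1274 well-covered arm bins, its log2 difference from their mean had an SD of 0.988, against 0.375 for replicate 2 minus replicate 3. A scale factor or composition effect that shifts all bins alike leaves such an SD nearly unchanged, so it is not the source of this spread. That follows from the arithmetic and is not a test. A composition effect that differs between bins stays open. Poisson counting of reads would give an SD of 0.0478, far below 0.988, which argues against read counting alone as the source. The SD of replicate 2 minus replicate 3 exceeds that value too, so an excess over counting is not particular to replicate 1. Sampling of few RNA molecules stays open. In the 425 bins where replicate 1 was most even, the SD was still 0.849, against 0.354, which argues against uneven coverage as the whole cause. A difference in library preparation, or in the RNA recovered, also stays open and was not tested.

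Replicate 1 also held a lower share of signal on M, U and XHet. On XHet this came mainly through the bin XHet 191001. On U it came in large part through U 9063001 to 9065000, with 0.695%, 7.80% and 7.77% in replicates 1, 2 and 3. Loss of compact blocks was tested on M: the median log2 difference was -3.63 over 2 broad bins and, since these were few, also -3.87 over a wider set of 9 bins that were not compact in replicate 2. Losing the whole of the strongest 200 bases would give no less than -0.918 in the 2 bins and -2.09 in the 9, and each of the 9 lay below its own such bound. Loss of several blocks per bin stays open on M, as does loss of compact blocks on U and XHet. Removal of duplicate reads would leave at most 100 reads over a base with reads of 50 bases, yet 504994 lay over 1 base of replicate 1.

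The 9 bins far higher in replicate 3 were nearly all narrow blocks. One amplified fragment per bin would rise at a single base, but the median largest rise was 0.229 of the pile-up height. In replicate 2, 88.9% of these bins (8 of 9) were compact, against 5.63% of the other 15526 measured bins (two-sided exact Fisher p = 8.96e-10). This test was chosen after the narrow blocks were seen and treats bins as independent, although 2L 13211001 and 2L 13212001 share 1 block, so it decides nothing. A class of short RNA and a few amplified fragments per bin both stay open.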

How the results depend on the processing

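Of 74 alternatives to the main values, 54 stayed within the limits set for them and 20 moved. The 54 include library-specific counts of 0 that stayed 0. They also include counts of 327 and 227 signal-rich bins, with a pseudocount 10 times lower and without centring. The tally alone is therefore not a measure of stability. The count of 277 signal-rich bins became 61 with a pseudocount 10 times higher, 514 with no filter, 462 with a filter 10 times higher, 900 at a 2-fold threshold and 70 with 5-kb bins. It ranged from 258 to 673 when 1 replicate was left out of the test but kept in the filter, and 673 was the count without replicate 1. Fewer bins were tested with 5-kb bins (4199) and the higher filter (1320), and more with no filter (78535). The cause of these changes in the count was not tested. With no filter, r was 0.902 for replicates 1 and 2 and 0.902 for replicates 1 and 3. The 119 higher and 263 lower bins of replicate 1 became 16 and 47 with the higher filter, 327 and 129 without centring, and 22 and 43 with the higher pseudocount. With a pseudocount 10 times lower they were 221 and 438, and with 5-kb bins 5 and 43. The 9 higher bins of replicate 3 became 1 with the higher filter. Without the highest 0.1% of bins, the arms held 97.6% of signal, U 0.999%, M 0.235% and XHet 0.0622%, as follows from leaving out the strongest blocks. On the arms alone, the top 1% of bins held 35.0%.

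Of 288 alternatives for the 25 named regions, 282 kept the region past the threshold. The other 6, all with the higher pseudocount, were XHet 191001, U 9063001, M 1001, M 12001, XHet 184001 and U 3545001. Their levels went from between 5.83 and 10.42 to between 4.36 and 8.88, and their SD between replicates, 1.54 to 2.95 before, was 1.36 to 2.78. The 25 regions were chosen as the highest in the same data. The 2-fold threshold could not lose a call, and the other filters left the levels unchanged. The 282 of 288 is therefore not a measure of robustness. After thinning to the shallowest library, an alternative added after the data were seen, 280 bins were called, of which 274 were among the 277. The filter was failed in replicate 1 alone by 1250 bins, in replicate 2, the shallowest library, by 1008, and in replicate 3 by 1244. Gene lists, intron over exon and their alternatives were not run. No paired analysis was possible because the series holds one group.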

Other observations

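Median differences of replicate 1 from the other libraries varied by sequence. Over 2726 measured bins of X, the median log2 difference of replicate 1 from the mean of the others was 0.147 (quartiles -0.386 and 0.733), against -0.097 (-0.614 and 0.455) over the 12464 bins of 2L, 2R, 3L and 3R. The spread of single bins was thus far wider than the gap between these medians. On the deposited scale the medians were 0.547 and 0.303, so the sign for the autosomal arms depends on centring. The gap, 0.244, cannot change with centring, which shifts all bins of a library alike. Chromosome 4 had a median of -0.609 (quartiles -1.07 and -0.172) over 156 bins, and of -0.209 without centring. Its median levels in replicates 2 and 3, -0.00238 and -0.256, also differed. Over the 13 measured bins of XHet the median was -0.449, and -0.0493 without centring. Of the 119 bins over 4-fold higher in replicate 1, 44 (37.0%) lay on X, which holds 17.5% of measured bins. These values describe 1 library against 2, and no test was made.

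Compact bins made up 51.4% of the measured bins of U and 38.5% of those of XHet, against 3.22% on the arms. Of the 14 called bins of U, 10 were compact, as were all 3 called bins of XHet, while 15 of the 253 called bins on the arms were.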
